A study of Salix matsudana with 3 samples.

How the data were processed

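The series holds 3 samples from roots and stems of 30-day-old Salix matsudana, the Chinese willow. A small RNA library was made from untreated plants, and another from plants exposed to 100 mmol per litre NaCl for 2 days. A degradome library, in which cleaved messenger RNA ends are sequenced, was made from RNA of both conditions mixed. Total RNA was extracted with a column kit and treated with DNase, and the small RNA libraries followed the standard Illumina protocol, per the labels' protocols. The read trimming, mapping, miRNA calling and degradome calling tools were not given in the sources used here.

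The small RNA table gave estimated read counts per mature sequence in columns marked raw, per the file headers. Of its 205 entries, 68 (33.2%) held parts of reads in at least 1 library, which points to shared reads divided between entries in the deposited estimated counts. Identical sequences listed under 2 names, 6 in all, carry identical counts. Whether their reads were divided or repeated is not given in the sources used here, and if repeated, shares and totals count them 2 times. The library columns name 0 and 2 days, and they were matched to the untreated and salt samples through the sample titles. Other columns gave the mature length and the precursor start and end, per the file headers. The degradome table gave raw counts of degradome reads at each cleavage position, per the file headers. Its alignment score ran from 0 to 4 per the file headers and values, with lower scores for better matches. It also held a deposited signal headed TPB, whose meaning the header does not spell out, and it was used only to see that 1 read was worth at most 52.7 units. The cleavage position on the target transcript was deposited without a transcript identifier, peak category or p-value.

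Estimated counts were divided by the library's total over the 205 listed entries and multiplied by 1000000. This level, relative to the listed reads, is written RPM. The listed total is not the full depth of a library, which was not used here. The total was 4622984 reads in the untreated library and 734026 in the salt library, so 1 read was worth 0.216 and 1.36 RPM. A count of 0 allowed up to 3 reads, which is 0.649 RPM in the untreated library and 4.09 in the salt library. Per entry, the log2 ratio of salt over untreated was taken on level + 1, among entries with a mean level of at least 10 RPM. A ratio of at least 2-fold was called higher and at most 0.5-fold lower. Ratios of shares without the added 1 carry 95% exact intervals from the conditional binomial distribution, after rounding estimated counts to whole numbers. Shares of a single library carry exact Clopper-Pearson intervals. Intervals and floors cover counting error only, because reads copied by PCR are not independent molecules.

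With 1 library per condition, no test between conditions was possible and no difference has a replicate check. A two-sided Fisher exact test of each entry against the rest of its library, with Benjamini-Hochberg adjustment over 205 entries, compared the 2 libraries and not the conditions. Families were formed by the number after miR and their members' levels were summed. The 9 miRNA lists were fixed before the data were examined: growth phase, auxin signalling, leaf and organ development, silencing machinery, copper-responsive, phosphate and sulphate, NF-Y regulator, F-box and other stress, and NB-LRR regulators. Each list's median was placed among 10000 random lists of the same size, matched on mean level in 4 bins, as a description of these libraries.

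Degradome targets were counted by gene symbol as deposited, ignoring case. The 17 target classes were fixed before the data were examined, as words in an annotation. The table held symbols in place of annotation words, so the symbol patterns that stand for each class were written after the symbols had been seen. The same holds for the patterns used to look up the textbook target of each conserved family. Having at least 1 degradome target was set against being higher or lower with a two-sided Fisher exact test over miRNA entries, which are not replicates.

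The entries named in the text follow a rule fixed before the data were examined. It takes the 10 highest and 10 lowest ratios past 2-fold, the 5 most abundant entries, up to 4 most abundant members per list, the 10 best degradome sites, and up to 3 best sites per list. Sites were to be ranked by category and deposited p-value first. They were ranked by reads alone here, with 1 site per symbol. Entries and sites outside the rule are named as chosen after their values were seen. Entry names are given as deposited at first mention, and the suffix is left out afterwards.

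Alternatives covered pseudocounts of 0.1 and 5, no level minimum or 50 RPM, thresholds of 1.5-fold and 4-fold, other scalings, counting identical sequences once, and thinning the untreated reads to the salt total. For the degradome they covered the alignment score, a minimum of 2 or 10 reads, repeated lines and the cleavage position. The ranges over 6 scalings compare the listed total with the median ratio, the total without the 5 most abundant entries, the total without miR6300, MIR2916, miR8175, miR5139 and MIR5141 entries as possible rRNA or tRNA fragments, the total without miR159, and distinct sequences. The rRNA and tRNA scaling and the miR159 scaling were added after the data had been seen, and so were all scalings of families and lists but the median ratio.

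The calculation was tested on simulated data drawn from the mean share of each entry and both library totals, with changes set among entries at the level minimum other than the most abundant. All 40 of 40 simulated 4-fold changes were called in the right direction, and 1 of 76 tested unchanged entries passed 2-fold. The Fisher test called 40 of 40 changed and 3 of 76 unchanged entries, and 192 of 199 intervals held the true ratio. These draws held counting error alone. They do not cover variation between libraries, or a shift of the most abundant entries that moves every other ratio. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used, with a fixed random seed. No genome was used, and precursor positions are those deposited, on contigs whose sequences were not used here.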

Results

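Small RNAs of Salix matsudana roots and stems were sequenced in 1 library from untreated plants and 1 library from plants given 100 mmol per litre NaCl for 2 days. The deposited table listed 205 miRNA entries with 199 distinct mature sequences in 76 numbered families. It included 42 predicted entries, whose names begin with PC. Precursors of 84 entries lay on contigs whose names have the form of long-read transcript isoforms. The listed entries held 4622984 reads in the untreated and 734026 in the salt library, a 6.30-fold difference in depth. A degradome library of the mixed RNA listed 981 pairs of a miRNA entry and a cleavage site. The series compares both conditions to find miRNAs that respond to salt and the genes they cleave. All differences between conditions rest on 1 library each and have no replicate check. No untreated library at 2 days was listed, so salt and the 2 days that passed cannot be told apart.

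A few conserved miRNAs held most reads in both libraries. The most abundant was ptc-miR166a, a regulator of HD-ZIP III transcription factors in leaf and vascular patterning. It took 45.9% of the untreated and 33.0% of the salt reads, 1.39-fold lower in the salt library (95% counting interval 1.39 to 1.40). Its mature sequence is TCGGACCAGGCTTCATTCCCC, and its precursor lay at positions 252 to 391 of contig c7191_f2p0_2748_2_3kb. The entries ptc-miR159a_R-1 and cpa-miR159a_R-1 share the sequence TTTGGATTGAAGGGAGCTCT and identical counts, and miR159 is known to restrain GAMYB transcription factors. Each stood at 132998 RPM in the untreated library and 22099.9 RPM in the salt library, 6.02-fold lower (5.92 to 6.11). In contrast, ptc-miR472b, a regulator of NB-LRR disease resistance genes, held 7.31% of the untreated and 18.1% of the salt reads. That was 2.47-fold higher (2.46 to 2.49), or 1.31 log2, which dropped below 2-fold without miR159 (0.92), with the median ratio (0.97) and without the 5 most abundant entries (0.33). The NB-LRR regulator ptc-miR1448_L+1R+1 was 5.002-fold higher (4.95 to 5.06), at 16164 and 80855 RPM. These 5 entries together took 81.5% of the untreated and 63.6% of the salt reads, and these shares count the miR159 sequence under both of its names.

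Among 115 entries at the level minimum, 37 were at least 2-fold higher in the salt library, 15 were at least 2-fold lower and 63 were neither. The Fisher exact test on reads, which compares the 2 libraries and not the conditions, gave an adjusted p below 0.05 for 85 of the 115, among them all 37 and all 15. The excess of higher entries depended on the scaling. The share of higher among called entries was 71.2% with the listed total and 34.4% (21 higher, 40 lower) without the 5 most abundant entries. It was 59.6% (31 and 21) with the median ratio and 57.4% (31 and 23) without miR159. Relative to the listed total, the median of all tested entries shifted by -0.96 log2 without the 5 most abundant, -0.38 without miR159, -0.33 with the median ratio, -0.17 with distinct sequences and 0.21 without possible rRNA or tRNA fragments. Under all 6 scalings, 22 entries stayed at least 2-fold higher and 11 at least 2-fold lower, while 39 changed sign. Called entries described as keeping their sign dropped below 2-fold under at least 1 scaling.

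**Figure D1:**
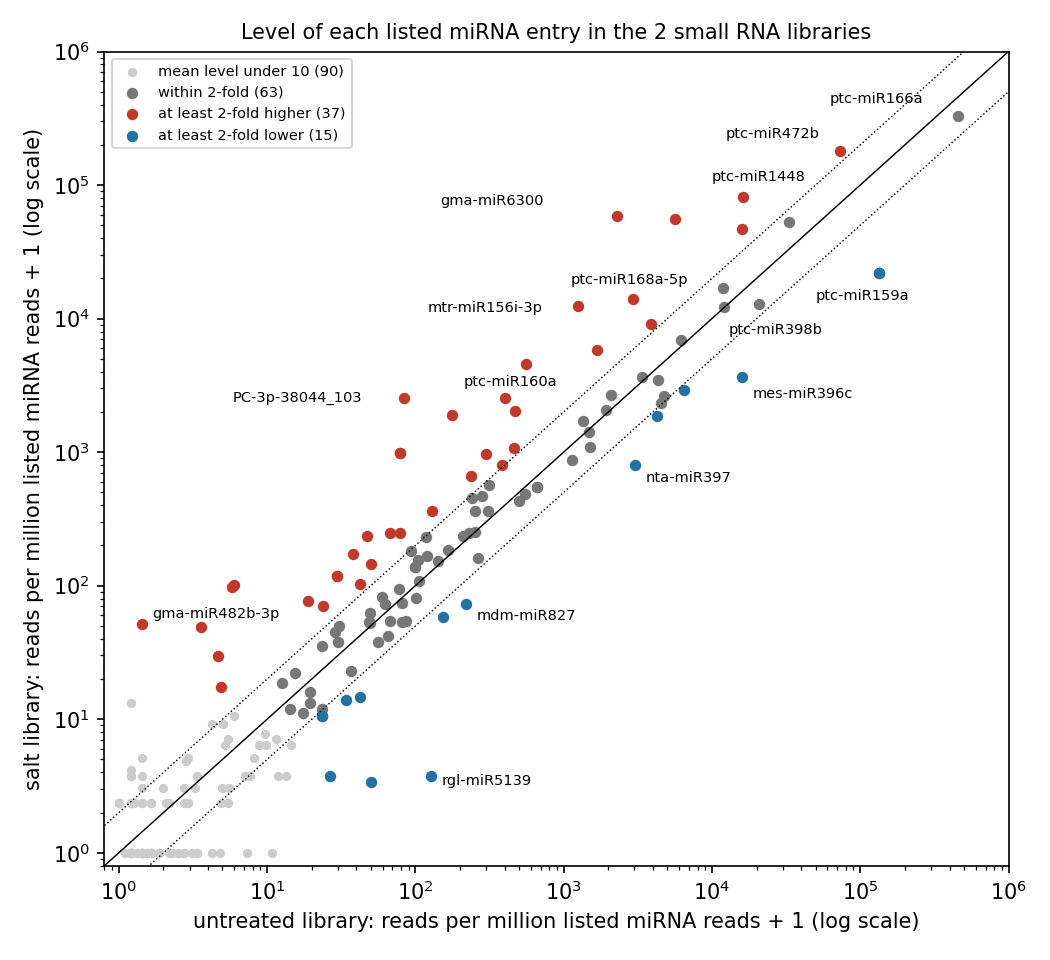
Each point is 1 of the 205 miRNA entries, with its level in the untreated library (horizontal) and the salt library (vertical) in RPM plus 1, both on log axes. The solid line marks equal levels and the dotted lines 2-fold; grey points lie under the level minimum. Of the 115 entries at the minimum, 37 lay at least 2-fold above and 15 at least 2-fold below, and without the 5 most abundant entries in the total the counts among entries at the minimum were 21 and 40.

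Each entry with a fold value in this paragraph stayed at least 2-fold higher under all 6 scalings. The entry gma-miR6300_R+5, with the sequence GTCGTTGTAGTATAGTGGTAAGT, stood at 2297 RPM in the untreated and 58887 RPM in the salt library, 25.6-fold higher (25.1 to 26.2), and it is treated separately as a possible tRNA fragment. The 3p arm mtr-miR156i-3p_3ss11T-13TC22TG, which held more reads than its partner arm ghr-miR156a_R+1 in both libraries, was 10.03-fold higher (9.71 to 10.4), and sly-miR164a-3p_2ss10GT12TC was 10.8-fold higher (9.89 to 11.8). The identical pair vvi-miR3630-3p_L-2_1ss22CT and han-miR3630-3p_L-2_1ss21TA was 12.6-fold higher (11.1 to 14.3). For ptc-miR160b-3p, 23 untreated and 74 salt reads gave a 20.3-fold higher share (12.5 to 33.9). The highest ratio was that of gma-miR482b-3p, with 2 untreated and 37 salt reads, a 117-fold higher share with an interval of 30.1 to 997.9. Predicted entries PC-3p-38044_103, PC-3p-132858_18 and PC-5p-83176_32 were 31.0-fold (27.8 to 34.8), 20.3-fold (12.4 to 34.4) and 18.4-fold (9.31 to 38.9) higher. PC-3p-38044_103 came from positions 1772 to 1909 of contig c2497_f2p2_1914_1_2kb. PC-5p-83176_32, with 12 untreated and 35 salt reads, came from positions 75 to 266 of contig c6106_f1p0_1330_1_2kb. These positions span the precursor deposited for ptc-miR408-3p_L-1R+1, at 130 to 232, so PC-5p-83176_32 need not be a separate locus.

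The lowest ratios, also at least 2-fold lower under all 6 scalings, were led by rgl-miR5139_L+2. Its 587 untreated and 2 salt reads gave a 46.6-fold lower share (12.8 to 385.7), and it too is treated separately as a possible rRNA or tRNA fragment. mes-miR159c_R-1_1ss1AT was 20.6-fold lower (4.93 to 149.7), and its salt level rested on 1.75 estimated reads. Its sequence differs at 1 base from that of the far more abundant ptc-miR159a, whose 6.02-fold lies within this interval. It therefore need not be a separate miRNA. mes-miR396c, a regulator of growth-regulating factors, was 4.42-fold lower (4.25 to 4.60), at 16014 and 3621 RPM. The laccase regulator nta-miR397_L+2 was 3.78-fold lower (3.48 to 4.11). mdm-miR827, known from phosphate signalling, was 3.03-fold lower (2.30 to 4.08), and ppe-miR395c, known from sulphate assimilation, was 2.68-fold lower (1.96 to 3.75). Predicted entries PC-5p-40981_92 and PC-5p-34594_120 were 9.45-fold (2.56 to 78.9) and 3.03-fold (1.61 to 6.43) lower, with 2 and 10 salt reads. Of the 16 predicted entries tested, 4 were higher and 4 lower, and PC-5p-85457_31 and PC-3p-85457_31 among the lower share their sequence and counts.

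Summed over members, 13 of 43 families were at least 2-fold higher, 7 were lower and 23 lay within 2-fold, and without the 5 most abundant entries 6 were higher and 17 lower. Under all 6 scalings miR6300, miR3630, miR156, miR160, miR2916 and miR168 stayed at least 2-fold higher. miR5139, miR159, miR397, miR396 and miR827 stayed at least 2-fold lower. The miR156 family sum stood 3.03 log2 above the untreated library, carried by mtr-miR156i-3p, while the median over its members was 0.53. The miR396 family sum of -1.64 was carried by mes-miR396c. The median over its members was -0.07, and gma-miR396a-5p_L+1 was 2.83-fold higher (2.54 to 3.16) with a constant sign. miR858, known from the control of MYB factors in phenylpropanoid synthesis, was 1.20 log2 below the untreated library. miR828, which also acts on MYB factors, was 1.66 log2 above it; both kept their sign under all 6 scalings and were singled out after their values were seen. Signs of 15 families changed with the scaling.

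**Figure D2:**
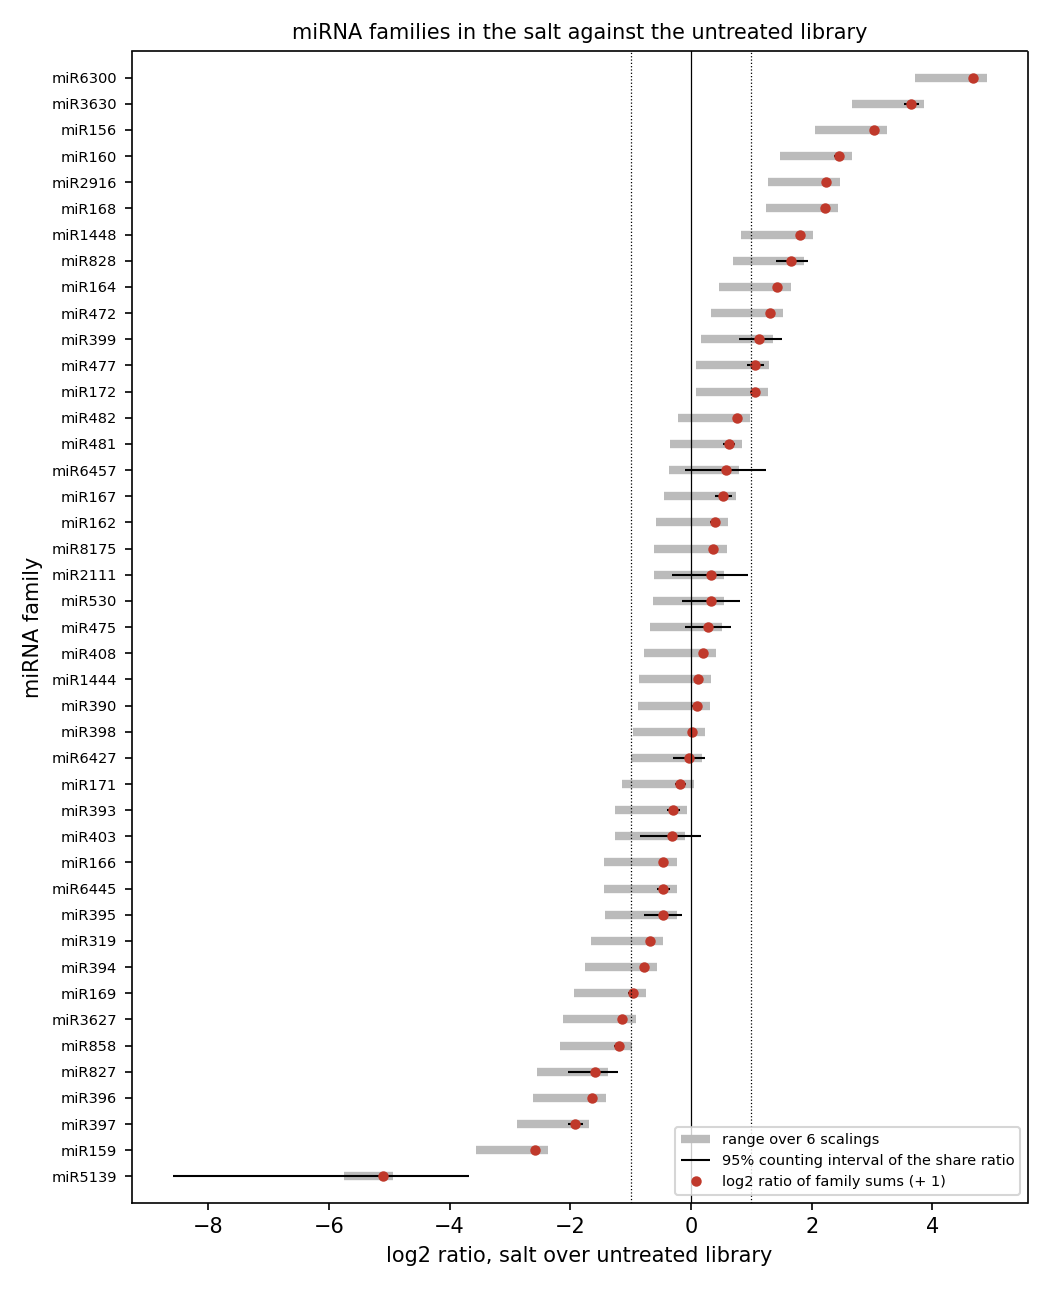
Points give the log2 ratio of salt over untreated for the sums of 43 miRNA families, black lines the 95% counting interval, grey bars the range over 6 scalings, the solid line no difference and dotted lines 2-fold. The 6 families at the top stay past 2-fold over the whole grey bar and 5 at the bottom do so below, while the bars of 15 families, among them miR482, miR398 and miR408, cross 0.

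Leaf and organ regulators held 77.5% of untreated and 41.4% of salt reads. Of 21 tested members 6 were higher, 5 lower and 10 within 2-fold, and without the 5 most abundant entries in the total 4 were higher and 12 lower. Their median log2 ratio was -0.22, at percentile 2.96 of random lists, and it ranged from -1.20 to -0.01 over the scalings. Besides miR159 and miR396, ptc-miR319a, which targets TCP factors that limit leaf cell division, was 1.62-fold lower (1.58 to 1.65) and kept its sign under all scalings. Members also went the other way, and those named next were singled out after their values were seen. nta-miR164a, the regulator of NAC factors in organ boundaries, was 2.33-fold higher (2.27 to 2.40) and kept its sign. The passenger arm ptc-MIR166j-p5, from the same hairpin as ptc-miR166a, was 8.18-fold higher (7.77 to 8.61) and past 2-fold under all scalings, with 2562 untreated and 3327 salt reads.

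Growth phase regulators miR156 and miR172 act on SPL and APETALA2-like factors in the change from juvenile to adult growth. Of 11 tested members 4 were higher and none lower, and 7 lay within 2-fold; without the 5 most abundant entries 1 of 9 was higher and 1 lower. The median was 0.91, at percentile 86.9 of random lists, and it turned to -0.06 without the 5 most abundant entries. ptc-miR172g-3p was 2.32-fold higher (2.13 to 2.51) and kept its sign under all scalings. aly-miR172a-3p was 1.89-fold higher (1.67 to 2.14) and ptc-miR172d 1.11-fold (0.919 to 1.34). The sign of both turned without the 5 most abundant entries, and that of ptc-miR172d also without miR159, with the median ratio and with distinct sequences. The higher miR156 family sum rested on the 3p arm mtr-miR156i-3p, while the 5p arm is the one known to act on SPL factors. The 5p entries ghr-miR156a_R+1 and ptc-miR156g_R+1, singled out after their values were seen, lay within 2-fold, at 1.95-fold (1.59 to 2.38) and 1.08-fold (0.876 to 1.32) higher. The sign of the former turned without the 5 most abundant entries, and that of the latter under every other scaling except that without possible rRNA or tRNA fragments.

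Among auxin signalling miRNAs, miR160 represses auxin response factors. ptc-miR160a was 6.28-fold higher (5.89 to 6.71), at 401 and 2520.3 RPM, and past 2-fold under all scalings. Its precursor lay at positions 234 to 331 of contig c18781_f1p0_2573_2_3kb. Another miR160 member, ptc-miR160e-3p, went the other way, 1.58-fold lower (1.08 to 2.38) with a constant sign, and was singled out after its values were seen. The identical entries mes-miR393c_R-1 and gma-miR393a, regulators of auxin receptors, were 1.22-fold lower (1.10 to 1.36) and kept their sign. ptc-miR390a, a trigger of tasiRNA from TAS3, was 1.09-fold higher (1.03 to 1.15), a sign that turned under every other scaling except that without possible rRNA or tRNA fragments. Of 11 tested members 4 were higher and none lower, against 4 and 4 without the 5 most abundant entries. All 4 higher with the listed total were miR160 entries, and 2 of these share a sequence and counts. With distinct sequences 3 of 9 were higher. With the listed total the list median was 0.17 at percentile 25.3, and it ranged from -0.80 to 0.39 over the scalings.

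The silencing machinery list was led by miR168, which targets ARGONAUTE1. ptc-miR168a-5p was 4.78-fold higher (4.66 to 4.90), at 2939 and 14044 RPM, and past 2-fold under all scalings, and ptc-miR168a-3p was 3.24-fold higher (2.96 to 3.55). ptc-MIR162a-p5 was 2.93-fold higher (2.30 to 3.70) and, like ptc-miR168a-3p, kept its sign. ptc-miR162a, which targets DICER-LIKE1, was 1.28-fold higher (1.20 to 1.36), and its sign turned without the 5 most abundant entries and without miR159. Of 6 tested members 3 were higher and none lower (1 and 2 without the 5 most abundant entries), with a median of 0.94 at percentile 78.7 that turned to -0.03 without the 5 most abundant entries.

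The NB-LRR list, drawn up as regulators of disease resistance genes in Salicaceae, took 13.7% of untreated and 33.8% of salt reads. Of 8 tested members 5 were higher and none lower, against 2 and 1 without the 5 most abundant entries, and 4 and 0 without miR159 or with the median ratio. The 1 lower was ptc-miR6445a, at -0.46 log2 with the listed total and -1.43 without the 5 most abundant entries. Its best degradome site lay in the NAC gene NAC089, not in a resistance gene. The median was 1.39, at percentile 93.4 of random lists, and it stayed above 0 over the scalings, from 0.42 to 1.61. Beside ptc-miR472b and ptc-miR1448, mes-miR482_1ss2CT was 1.60-fold higher (1.58 to 1.62), and ptc-MIR1448-p5_1ss21CT was 1.42-fold higher (1.39 to 1.45). Both signs turned without the 5 most abundant entries, 2 of which belong to this list.

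Among 11 copper-responsive entries 1 was higher and 1, nta-miR397, lower (1 and 2 without the 5 most abundant entries). The superoxide dismutase regulator ptc-miR398b was 1.01-fold higher (0.984 to 1.03), ptc-miR408-3p_L-1R+1 1.12-fold (1.09 to 1.16) and ppe-miR398a-5p_2ss11GC12GA 1.18-fold (1.03 to 1.34), and these signs turned without the 5 most abundant entries, without miR159 and with the median ratio, and those of ptc-miR398b and ptc-miR408-3p also with distinct sequences. The copper list median was 0.23 at percentile 34.3, from -0.73 to 0.45 over the scalings, while its summed share was 1.06-fold lower. Of 6 phosphate and sulphate entries, 2 were higher and 2 lower, and without the 5 most abundant entries 0 and 2. ptc-miR399e, a regulator of the phosphate gene PHO2, was 2.47-fold higher (1.86 to 3.23) and ptc-MIR395d-p5 3.03-fold higher (2.13 to 4.27), both with a constant sign. The phosphate and sulphate median was 0.44 at percentile 60.9, from -0.49 to 0.65, while the summed share was 1.33-fold lower. In the NF-Y list, ptc-miR169ac_R+2 alone was tested and was 1.96-fold lower (1.86 to 2.06), with a log2 ratio of -0.97 at percentile 22.6 and a range of -1.94 to -0.75. ptc-miR169z_L-1R+2_1ss14TC had 1 read in each library. In the F-box list, ptc-miR394a-5p was 1.78-fold lower (1.70 to 1.87) with a constant sign. Its partner ptc-MIR394a-p3_1ss16TC was 1.40-fold higher (1.14 to 1.71), a sign that turned without the 5 most abundant entries. The F-box median of -0.17 lay at percentile 29.5 and ranged from -1.15 to 0.05.

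The miR6300, MIR2916, miR8175, miR5139 and MIR5141 entries, 7 in all, took 2.61% of untreated and 16.4% of salt reads. They were grouped after the data were seen as possible fragments of rRNA or tRNA, and their sequences were not compared with rRNA or tRNA here. The place of rgl-miR5139 in this group is uncertain, because it shares a stretch with a listed miR1511 entry. The grouping went by family number, which predicted entries lack, so it could not include them. Sequences of predicted entries were not compared with rRNA or tRNA either. peu-MIR2916-p5_1ss5AG was 9.87-fold higher (9.72 to 10.03) and past 2-fold under all scalings, and peu-MIR2916-p3_2ss13CT19GC was 2.93-fold higher (2.89 to 2.97) with a constant sign. The untreated reads of both MIR2916 entries summed to exactly 100000. A limit of 100000 reads on every entry or precursor is argued against by the untreated counts. ptc-miR166a held 2124195 reads, and the miR1448 entries, from a single precursor, together held 130004. Whether a limit was applied to MIR2916 alone is not given in the sources used here, and such a limit would overstate the miR2916 ratios. Reads of 38 entries seen in the untreated library were 0 in the salt library, against 39.4 expected from depth alone at equal shares. None of these 38 reached the level minimum. Among them aly-miR158a-3p, singled out after its values were seen, had 45 untreated reads and was at least 2.38-fold lower in the salt library against a floor of 3 salt reads, with the untreated reads taken as exact. The 95% exact interval, which counts the error of both libraries, began at 1.86-fold lower. aly-miR158a-3p alone had a Fisher adjusted p under 0.05 between the libraries (Fisher exact test, adjusted p = 0.0054), and none of the other 37 reached that threshold at this depth. ath-miR5642a_R+4, also singled out after its values were seen, had 29 untreated reads (Fisher exact test, adjusted p = 0.060). Its 95% exact interval, not adjusted for the number of entries, ended at a share ratio of 0.854.

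The degradome library listed sites for 100 miRNA entries and 190 named target symbols. The strongest were the auxin receptor genes AFB2 and TIR1, each cut opposite base 10 of gma-miR393a, at positions 3030 and 1288 of their transcripts, with the same 1137 reads. A site of the same miRNA in Os05g0150500 had 667 reads. aly-miR172a-3p cut the flowering and growth phase gene AP2 at position 1934 with 510 reads, RAP2-7 with 86 and TOE3 with 22. ptc-miR1448 cut the resistance genes RGA2 with 306 reads and RPP8L4 with 285, both at the highest listed alignment score of 4. ptc-miR160a cut ARF18 and ARF16 with 237 reads each and ARF8 with 236. ptc-miR394a-5p cut the F-box gene FBX6 with more than 100 reads, and WRKY19 and BHLH49 were listed with 14 reads and 1 read. ptc-miR166a cut HOX32, ATHB-14 and ATHB-9 with 109 reads each.

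Weaker sites covered the other lists. nta-miR398_R+2 was listed at LAC9 with 78 reads, and nta-miR397 cut the laccase genes LAC5 with 21 and LAC16 with 10. aly-miR395c-3p_1ss17GA, with 2 untreated reads and none in the salt library, was listed at the ATP sulfurylase genes APS1 and APS3 with 84 reads each and a score of 4. ptc-miR2111a cut At3g27150 with 31 reads. ptc-miR169ab_1ss11AT, with 1.5 untreated reads and none in the salt library, was listed at NFYA7 and NFYA1 with 28 reads each and NFYA8 with 11. ptc-miR403a_1ss19TC cut AGO2 with 25 reads, and hpe-miR162a_R+1 cut DCL1 with 5. ptc-miR6445a, placed in the NB-LRR list, was listed at the NAC gene NAC089 with 34 reads. The same reads are listed for several symbols and for entries of similar sequence, so sites are not independent. No site carries a comparison between conditions, because the degradome RNA was mixed.

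Sites differed widely in depth. The median site had 6 reads, 243 of 981 (24.8%) had 1 read, and 78 had at least 100. Counted back along the target from the end of the alignment, cleavage lay at position 10 in 863 pairs (88.0%), 9 in 62 and 11 in 56. Gaps in the alignment were not allowed for, so positions 9 and 11 need not differ from base 10 of the miRNA. Whether the site calling required a position is not given in the sources used here. Sites of the 9 lists, 706 in all, had a median of 12 reads, and the other 275 had a median of 2. Predicted entries had 94 sites from 16 entries, with a median of 2 reads and at most 25.

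The 17 target classes matched 90 of 190 named symbols (47.4%, exact Clopper-Pearson interval 40.1 to 54.7). This is not the share of known miRNA targets, since textbook targets such as UBC24, APS1 and APS3 lay outside the classes. NB-LRR genes gave 12 symbols, transporters 10, GRAS genes 8, and HD-ZIP III factors, laccases with copper proteins, and kinases 7 each. ARF genes, NF-YA subunits and argonaute or dicer genes gave 6 each, and SPL factors 5. AP2-like, TCP and NAC factors gave 3 each, MYB, GRF and auxin F-box genes 2 each, and PPR genes 1. The highest kinase site had 2 reads, and the median transporter site 1. Of 24 conserved families looked up, 22 had sites and 19 of these included the textbook target, such as SPL factors for miR156, scarecrow-like genes for miR171, and UBC24 for miR399. miR167, miR398 and miR408 had sites at other symbols or unnamed targets only, and miR168 and miR827 had none.

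**Figure D3:**
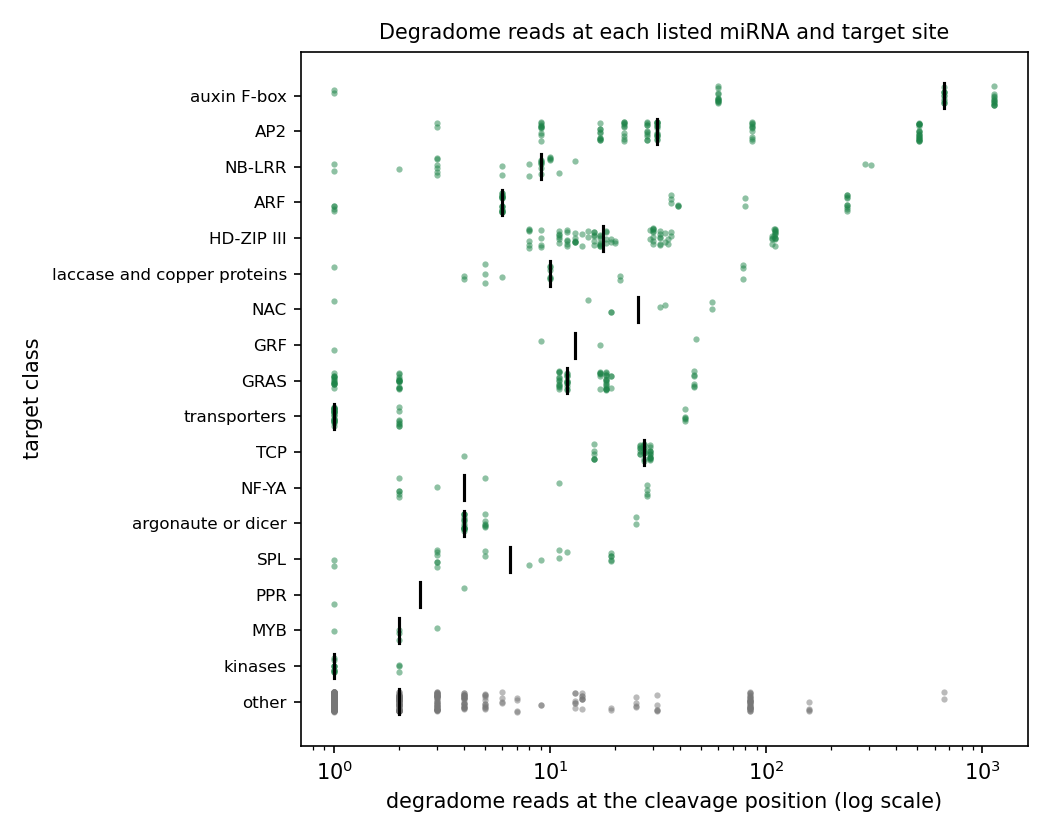
Each point is 1 listed miRNA and target site with a named symbol, placed by its degradome reads (horizontal, log scale) and its target class (vertical, with random spread within a class), and black bars mark class medians. Auxin F-box sites reach 1137 reads and AP2 sites 510, while kinase sites stay at 2 or fewer.

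Whether miRNAs with a cleavage site were over-represented among the called entries was tested over the 115 entries. Among entries higher in the salt library, 18 of 37 (48.6%) had a degradome target, against 50 of 78 (64.1%) of the others. The odds ratio was 0.53, with a two-sided Fisher exact p = 0.155 and an adjusted p = 0.272 over the 2 tests. Among lower entries, such as miR159, mes-miR396c and nta-miR397, 11 of 15 (73.3%) had a target, against 57 of 100 (57.0%). The odds ratio was 2.07, with a two-sided Fisher exact p = 0.272 and an adjusted p = 0.272, and it was 0.391 (p = 0.250) with alignment scores of at most 3. No difference in either direction was detectable with these numbers, and entries are not replicates. Identical sequences were counted under both names, such as the miR159 pair among the lower and the miR3630 pair among the higher entries.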

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

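Thinning, the rRNA and tRNA and miR159 scalings, all scalings of families and lists but the median ratio (among them distinct sequences), the arm alternatives, the read minimums, repeated lines, the cleavage position, and the score limit on target classes and on the odds ratios were chosen after the data had been seen. With 37 higher and 15 lower entries as the reference, a 4-fold threshold gave 20 and 6, by construction, and a 1.5-fold threshold gave 25 lower. Without a level minimum 34 were lower, and with 50 RPM 9 were. Totals without the 5 most abundant entries gave 21 higher and 40 lower, and without miR159 23 lower, because each lowers every ratio by a common factor. Without the 5 most abundant, 6 families were higher and 17 lower, in place of 13 and 7. Among families, miR3627 turned from -1.14 to 0.34 when the median over its 2 members replaced the sum, since the sum is carried by its abundant member (-1.15 alone). The number of lists at least 2-fold higher went from 1 to 2 with family sums, 3 without possible rRNA or tRNA fragments and 0 without the 5 most abundant, where 1 list in place of 6 had a median above 0. Arm intervals below 0 went from 9 to 3 when reads were summed per arm over entries at 1 locus and only loci on a contig were kept. An alignment score of at most 3 left 479 sites, 54 miRNA entries and 78 targets; at least 10 reads left 420, 39 and 60; at least 2 reads left 126 targets. The percent of targets in a class was 57.4 over miRNA and target pairs, 59.5 with at least 2 reads and 74.4 with a score of at most 3. The odds ratio for lower entries, 2.07, turned to 0.391 with that score limit; the cause was not tested. The other 62 values for counts, lists, sites, arms and odds ratios stayed within 1.5 times or kept their direction. For named entries, 229 values lay within the counting interval and 173 outside it, with no called sign turned; for families the counts were 89 and 211. Restricting to peak categories or deposited p-values was not run. Rescaling to the same listed total equals the scaling used and moves nothing. No paired analysis was possible because each condition has 1 library. Depth limits low entries: 1 salt read is worth 1.36 RPM.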

Other observations

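The length classes, arm ratios, tRNA pairing and all explanations below were chosen after the counts had been seen. Of 24 tested entries of 22 nucleotides, a length known to trigger secondary siRNAs, 10 were higher and 1 lower, with a median log2 ratio of 0.69. The 64 entries of 21 nucleotides had a median of 0.23 (19 higher, 8 lower) and the 11 of 20 nucleotides -0.56 (4 higher, 3 lower). The 9 entries of 24 nucleotides had 0 higher and 2 lower, with a median of 0.12. Those 2, PC-5p-85457_31 and PC-3p-85457_31, share 1 sequence and its counts. At 20 nucleotides the lower entries were all miR159, including its identical pair, and the higher ones included the identical miR3630 pair. The 5 entries of 23 nucleotides had a median of 0.57 (2 higher, 1 lower), and both entries of 25 nucleotides, PC-3p-38044_103 and PC-3p-132858_18, were higher. Without the 5 most abundant entries in the total, the medians at 20 to 24 nucleotides all fell below 0, to -1.44, -0.73, -0.27, -0.39 and -0.85 in order of length. No test compared the lengths, and the 22-nucleotide group includes NB-LRR regulators such as ptc-miR472b, ptc-miR1448 and mes-miR482.

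Ratios between entries deposited as arms of 1 precursor, which no common scaling can move, differed between the libraries. A mature sequence can hold reads of several loci, and mes-miR396c held parts of reads, so a ratio need not measure 1 hairpin. Among the pairs compared is MIR2916, grouped above as possible rRNA or tRNA fragments, with an interval that excludes no change. In 26 pairs of entries deposited under 1 precursor number, with at least 20 reads of each entry over both libraries together, the minor arm's share was higher in the salt library for miR166 (0.120% to 1.36%), miR164 (4.31% to 17.3%) and miR396 (8.50% to 28.2%), and was lower for miR1448 (42.5% to 17.4%); the miR164 and miR396 pairs have no contig position. Counting error is argued against, since 20 exact intervals excluded no change, and a common rise of minor arms, the idea first looked for, is argued against by 9 intervals below 0 (7 when the minor arm is set by the untreated library, and 8 of 25 when reads are summed per arm over entries at 1 locus, which merges 2 miR172 pairs and turns miR398 above 0, or 3 of 13 with a contig position). Saturation of abundant sequences may contribute and cannot be told apart: across pairs, which are not independent replicates, in the single relation examined, Spearman's rho with the major arm's level was 0.33 (permutation p = 0.095) and Pearson's r 0.41 (permutation p = 0.041, and r = 0.39 without the 2 farthest). Salt treatment stays open and untested, because each condition is a single library and no untreated library at 2 days is listed.

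gma-miR6300 was 25.6-fold higher while ath-miR8175_L+1_1ss3AT, with the sequence CGTTCCCCGGCAACGGCGCCA, was 1.29-fold higher (1.23 to 1.35), a sign that turned without the 5 most abundant entries and without miR159. A candidate explanation is that both are ends of a single tRNA: the first 7 bases of the former pair at 7 of 7 positions, 1 of them G:U, with the 7 bases before the last 4 of the latter, as in an acceptor stem, and 1 of 198 other sequences pairs as well. Even breakdown of that tRNA is argued against, because the log2 ratios differed by 4.31 (4.24 to 4.39). Uneven survival of tRNA ends, from salt or from sample handling, was not tested.

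More entries were higher than lower, and this excess depends on the total used. Leaving entries out of the total moves every other ratio by a common factor that their shares fix, so the changed counts test nothing by themselves. Through the total, possible rRNA and tRNA fragments work against the excess, because their share was larger in the salt library (2.61% and 16.4%). Leaving them out moves the other ratios by 0.22 log2, upwards. They also enter the counts themselves: gma-miR6300 and both MIR2916 entries were called higher, and rgl-miR5139 lower. That contribution was not tested, so fragments are not argued against as a source. The 5 most abundant entries (-0.98) and miR159 alone (-0.38) cannot be told apart from an effect on most miRNAs. Such an effect could come from salt or from the 2 days that passed. No outside standard for total miRNA was used here.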
